A study of Mus musculus with 6 samples.

How the data were processed

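RNA was sequenced from D2.OR cells, a mouse mammary carcinoma line, carrying a lentiviral scrambled short hairpin RNA (Scram) or a hairpin against Slx4ip (shSLX4IP). Per the labels' protocols, 31500 cells per cm2 were plated on solidified Cultrex, a basement membrane extract, in medium with 10% serum and 5% Cultrex, and were harvested after 7 days. Libraries were made from 1 µg of total RNA with a stranded poly(A) kit. There were 2 groups of 3 samples. The labels call the replicates biological and do not say whether they came from separate cultures. The p-values set the difference between the groups against the spread within them, and part of that spread can be technical.

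The submitters' processing notes name fastp 0.19.5, STAR 2.7.7, StringTie 2.1.7 and DESeq2 1.22.1 and the build GRCm38 (mm10). The annotation release, the filters, the strand setting of the counting and the role of each tool are not given in the sources used here. The deposited values are a normalised signal per gene, that is, read counts divided by 1 size factor per library, as the file's name and its values show. The low values of each column are whole multiples of 1 step, worth 1.46 in Scram A, 0.934 in Scram B, 0.911 in Scram C, 0.906 in shSLX4IP A, 0.976 in shSLX4IP B and 0.796 in shSLX4IP C. Divided by that step, 99.98% (Scram A) to 100% of the deposited values above 0 in a library lay within 0.1 of a whole number. The recovered depth was 6110599, 6112569 and 6554748 reads in Scram A, B and C, and 5824441, 5433573 and 6693111 reads in shSLX4IP A, B and C. The columns carry the letters A, B and C and the labels carry replicate numbers. A letter therefore names a library of its group here, and it is not tied to a number.

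The table holds 53647 Ensembl gene identifiers with version numbers, of which 52094 matched a gene of GENCODE M21 (GRCm38) without regard to version. The full identifier with its version matched for 35 of them, all 35 mitochondrial. Of the 53647 features, 36965 were listed at 0 in every library. Among 727 genes of families that every cell uses (ribosomal proteins, proteasome, translation factors and the like, by name patterns), many were listed at 0 or near it, Actb and Eef1a1 among them. The protein-coding genes were therefore ordered along each chromosome of GRCm38, and a gene with a mean value of at least 1000 over the 6 libraries scored 3 and any other -1. Maximal-scoring segments of at least 30 were kept. There were 4 of them, scoring 191, 65, 54 and 41. The highest score of any other segment was 18, and the highest in 100 shuffles of the values over the genes was 15. Genes lying wholly inside these segments and the mitochondrial genes are called placed genes below. This rule used the mean of all 6 libraries and no group difference, and it was chosen after the values were seen. A mean of at least 300 was also tried. It gave 9 segments, of which 5 were not found at 1000 and scored 32 to 80, with a highest score of 27 in the shuffles. The stricter value was kept by judgement. The highest-scoring of those 5, on chromosome 19, had 38.5% of its genes at 300 or more. Shares of high genes per window and a hidden Markov model were also looked at while the rule was chosen, and are not used here. Inside the segments 0 of 28 ubiquitous genes were listed at 0 and 27 had a mean of at least 100. Outside them 299 of 699 were listed at 0 and 145 had a mean of at least 100. This contrast follows in part from the choice of segments by their high values. Where exons overlap those of another gene, reads of the pair cannot be told apart on 1 strand, nor across strands if the counting did not use strand. Gene symbols are used only for placed genes, except where a feature is said to lie outside. Coordinates are those of GENCODE M21 on GRCm38.

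Features with a mean value of at least 10 were tested, 8127 in all, of which 8096 had an M21 gene and 462 were placed (431 in the segments and 31 mitochondrial). The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1) with an intensity trend, 2-sided, without a block. Benjamini-Hochberg adjustment ran over all 8127 features, with a threshold of 0.05. A fold change is on the log2(value + 1) scale, which understates the change of low genes. It is written as shSLX4IP over Scram, with the standard error (SE) of the limma fit. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, for lists with at least 5 tested members. The 37 lists were fixed before the data were examined, as were the main test, the first set of other settings and the rule for named genes. That rule took Slx4ip, the 10 genes highest and the 10 lowest by log2 fold change among genes with a symbol other than Gm or Rik names, a mean of at least 50 in the higher group, an adjusted p under the threshold and no overlap between the groups. It also took up to 4 members per described list, and Tert, Terc and Slx4. Its restriction to placed genes came after the values were seen. Without it the rule would have taken 1 placed gene among the 10 highest and 3 among the 10 lowest.

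The other settings chosen then were pseudocounts of 0.5 and 5, no filter beyond a value above 0, a mean of at least 50, TMM factors, quantile normalization, limma without the trend, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, each library left out, and a block. Those added after the values were seen were adjustment over placed features only, removal of a trend with exonic length and the segment threshold of 300. The test was tried on simulated reads for the same 8127 features, with 100 features changed 2-fold and 100 changed 4-fold. With the dispersion of the 5 libraries other than Scram A, limma called 13% of the 2-fold and 44% of the 4-fold changes, all with the right sign, and made 4 false calls among 61. With the dispersion of all 6 libraries it called 0 features of either size. At that dispersion edgeR also called 0 of both sizes, and DESeq2 called 1% of the 2-fold and 39% of the 4-fold changes with 44 false calls among 84. Far fewer features were changed than the 1872 called in the real data, and by at most 4-fold. The adjustment depends on both, so these shares do not measure the power of the tests on the real values. No 2 libraries were copies of each other, since a chi-square test over features gave at least 20.7 per degree of freedom for each pair within a group. All columns of per-sample values were used. Python 3.11.15 and matplotlib 3.10.9 drew the figures.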

Results

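D2.OR cells, a mouse breast cancer line used as a model of dormant disseminated tumour cells, were grown in 3D culture for 7 days with a scrambled hairpin (Scram, n = 3) or a hairpin against Slx4ip (shSLX4IP, n = 3). SLX4IP binds the nuclease scaffold SLX4 and has a role in telomere maintenance. The design asks how depletion of SLX4IP changes the transcriptome of these cells. Each library held between 5433573 and 6693111 recovered reads. Scram A had 8464 features above 0, Scram B 10947 and Scram C 10548, against 11611, 11334 and 11605 in shSLX4IP A, B and C.

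The targeted gene gave no check of the labels. Slx4ip (ENSMUSG00000027281.17, chromosome 2, 136891218 to 137071950) was listed at 0 in all 6 libraries, and so was its partner Slx4. Both lie outside the 4 segments in which gene symbols are used here, where Actb, Eef1a1, Rplp0, Ppia, Hsp90ab1 and Tmsb4x were also listed at 0 in all 6 libraries. The identifier of Gapdh, outside as well, was listed at 515, 481 and 441 in Scram A, B and C. In shSLX4IP A, B and C it was at 269, 266 and 296, and these values cannot be read as Gapdh. With 6 equal values the exact permutation test gave p = 1, and 3 samples against 3 cannot give a 2-sided p below 0.1. The feature under the identifier of Tert, the telomerase catalytic subunit, also lies outside. It was listed at 0, 644 and 479 in Scram A, B and C and at 467, 272 and 431 in shSLX4IP A, B and C, values that cannot be read as Tert. Terc had no row under its M21 identifier and is not analysed here.

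**Figure D1:**
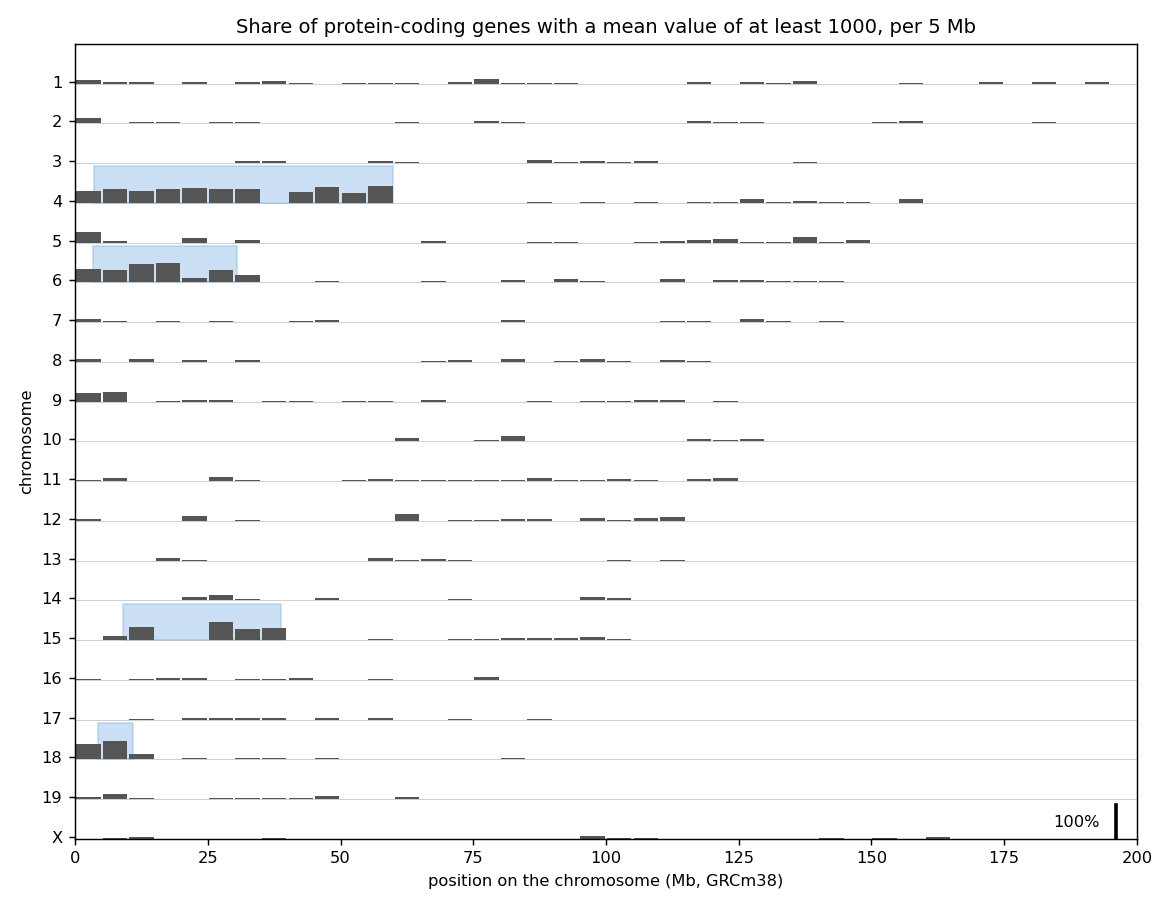
Percent of protein-coding genes with a mean deposited value of at least 1000 over the 6 libraries, in windows of 5 Mb with at least 5 genes, along each chromosome of GRCm38 (the black bar at the lower right marks 100%). Blue boxes mark the 4 segments, in which 38.7% to 63.0% of the genes reached 1000, against 3.53% of the genes outside.

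The 4 segments were chromosome 4 from 3574875 to 59904737 with 329 protein-coding genes, chromosome 6 from 3372257 to 30509783 with 119, chromosome 15 from 9071260 to 38692446 with 94, and chromosome 18 from 4375592 to 10818704 with 27. Of the 462 placed features tested, 80 were higher and 106 lower in shSLX4IP at the adjusted threshold of limma. At least 2-fold changes made up 65 of the higher and 76 of the lower. Over all 8127 features tested, 952 were higher and 920 lower, with 868 and 778 at least 2-fold. The values of the groups did not overlap in 310 placed features (67.1%) and in 4352 of all features tested (53.5%). Chance gives 10% for a single feature, and features are not independent. Without Scram A, 134 placed features were higher and 167 lower. Without 1 of the shSLX4IP libraries the counts fell to between 40 and 43 higher and between 58 and 60 lower, and without Scram C they were 58 and 69. Over all features they were 1895 and 1573 without Scram A, 641 and 489 without Scram C, and 433 to 441 and 410 to 418 without a shSLX4IP library.

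The deposited values of the 10 lowest placed genes fell in shSLX4IP to a small fraction of those in Scram, and a gene of type I collagen had the highest values among them. Col1a2 (ENSMUSG00000029661.17, chromosome 6, 4504814 to 4541544), which encodes a chain of type I collagen, fell from 23243 ± 2627 in Scram to 271 ± 31.4 in shSLX4IP (mean ± SD, n = 3 each; log2 fold change -6.42, SE 0.16, limma adjusted p = 7.64e-05). It was the one placed and tested member of the fibroblast list and 1 of 2 in the mesenchymal list. Matn2, a matrix protein of the matrilin family on chromosome 15, went from 1088 ± 44.5 to 4.73 ± 4.42 (log2 fold change -8.10, SE 0.88), a fold change that was -7.10 without shSLX4IP B and -8.75 without shSLX4IP C. Colec12, a scavenger receptor on chromosome 18, went from 3317 ± 173 to 30.6 ± 17.5, and Tspan12, a tetraspanin that takes part in norrin signalling through a Frizzled receptor, from 1306 ± 62.0 to 13.7 ± 8.08. The Wnt receptor gene Fzd8 was at 146, 123 and 153 in Scram A, B and C and was listed at 0 in each shSLX4IP library. Basp1, which encodes a membrane-associated protein of the growing axon, was at 395, 161 and 270 in Scram and listed at 0 in shSLX4IP. Hrct1 was at 455, 109 and 170 in Scram and listed at 0 in shSLX4IP. Ncald, a neuronal calcium sensor gene, fell from 458 ± 69.1 to 2.12 ± 3.68 (log2 fold change -7.87, and -8.83 without shSLX4IP C), and Ankrd33b from 230 ± 42.6 to 0.651 ± 1.13. Cox6c (ENSMUSG00000014313.16, chromosome 15, 35925886 to 35938246), a subunit of cytochrome c oxidase, was at 8256, 2909 and 3553 in Scram A, B and C and between 33.2 and 37.4 in shSLX4IP. Its value is uncertain because its exons overlap those of Vps13b on the other strand and the genome holds the related gene Cox6c2. Exons of Matn2, Tspan12 and Ncald likewise overlap those of other annotated genes on the other strand, and those of Ncald also a gene on the same strand. The adjusted p of these 10 genes lay between 7.64e-05 and 0.00296.

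Of the 10 highest placed genes, 6 were listed at 0 in each Scram library. Cped1 (ENSMUSG00000062980.16, chromosome 6, 21985916 to 22256404) was listed at 0 in each Scram library and at 570, 631 and 644 in shSLX4IP A, B and C (limma adjusted p = 0.000203), and its exons overlap a gene on the other strand. Cntfr, which encodes the ciliary neurotrophic factor receptor, was listed at 0 in Scram and at 244, 240 and 270 in shSLX4IP. Dlx5, a homeobox transcription factor of bone development, was listed at 0 in Scram and at 141, 184 and 155 in shSLX4IP. Fam71f1, Fam71f2 and Car8 were likewise listed at 0 in each Scram library, with means of 162, 52.3 and 64.6 in shSLX4IP. The zinc finger transcription factor gene Plag1 rose from 2.13 ± 3.68 to 372 ± 62.5 (log2 fold change 7.57, and 8.53 without Scram C). Tspan33 rose from 26.3 ± 22.1 to 615 ± 61.6, Prrt4 from 9.02 ± 8.22 to 133 ± 13.3, and Ica1, an islet autoantigen gene, from 237 ± 65.8 to 2717 ± 209 (log2 fold change 3.55, SE 0.23). The log2 fold change of Tspan33 was 4.82, and 5.45 without Scram A, and that of Prrt4 was 4.50, with 5.27 without Scram A and 3.22 without Scram B. The call of Prrt4 (adjusted p = 0.0389) was lost in 8 of 18 other settings, among them without Scram C or any 1 shSLX4IP library (0.0719 to 0.134), and the other 9 genes kept theirs in each setting in which they were tested.

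**Figure D2:**
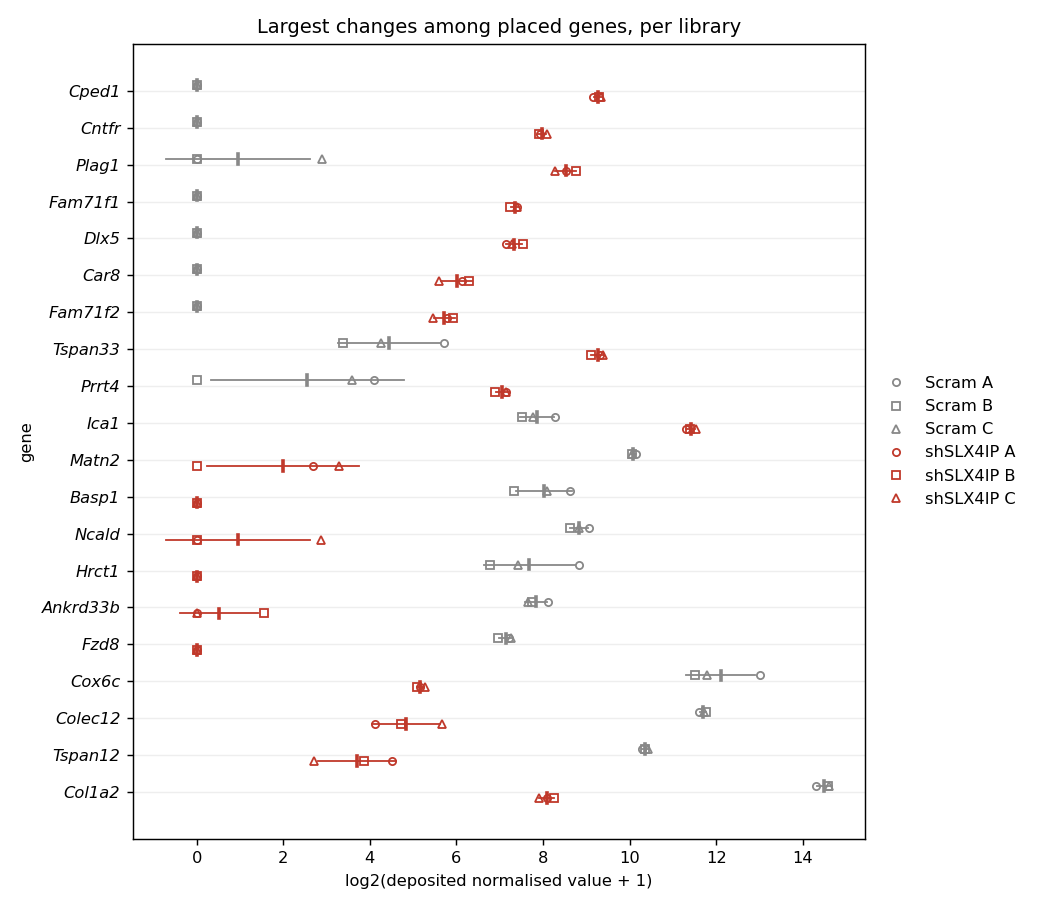
Values of the 10 highest and 10 lowest placed genes in each library, as log2(deposited normalised value + 1). Grey symbols are Scram and red symbols shSLX4IP, with a symbol per library letter, a vertical tick at the mean and a bar of 1 SD to each side (n = 3). The groups do not overlap in any of the 20 genes, a property the genes were chosen by.

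The lists fixed beforehand could be read only through their placed members, 19 nuclear and 13 mitochondrial genes. Among telomere and DNA repair genes, Pot1a (ENSMUSG00000029676.16, chromosome 6, 25743737 to 25809246), the shelterin subunit that binds single-stranded telomeric DNA, rose from 948 ± 5.63 to 2333 ± 110 (log2 fold change 1.30, SE 0.12, adjusted p = 0.00189). Nbn, a subunit of the MRN complex that acts at double-strand breaks and telomeres, fell from 2503 ± 292 to 987 ± 22.5 (log2 fold change -1.33, SE 0.14, adjusted p = 0.00283). With a trend with exonic length removed, its log2 fold change was -0.66 and it kept its call. Fancg, of the Fanconi anaemia core complex, was at 478 ± 86.9 and 603 ± 29.7 and did not pass (adjusted p = 0.241). Both placed p53 targets rose. Trp53inp1 went from 220 ± 45.0 to 890 ± 79.4 (adjusted p = 0.00291) and Rrm2b, a subunit of the p53-inducible ribonucleotide reductase, from 402 ± 86.7 to 1044 ± 79.6 (adjusted p = 0.00843). Ccne2, the cyclin E2 gene of S-phase entry, fell from 1656 ± 234 to 616 ± 8.96 (adjusted p = 0.00329), and its exons overlap those of Ints8 on the other strand, as those of Rrm2b overlap another annotated gene. Ddx58, the RIG-I sensor gene in the interferon list, rose from 4525 ± 681 to 8369 ± 226 (adjusted p = 0.0102). Its call was lost in 4 of 18 other settings (adjusted p up to 0.0658), among them without any 1 shSLX4IP library (0.0555 to 0.0602).

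The immediate early, hypoxia, basal and RNA interference lists had 1 placed tested member each, and each of these genes fell. The 1 placed tested member of the epithelial list and that of the TGF-beta list did not pass, nor did the mesenchymal member other than Col1a2. Single genes do not give the direction of a list. Klf4 (ENSMUSG00000003032.9, chromosome 4, 55527143 to 55532466), a pluripotency and epithelial transcription factor, fell from 3038 ± 127 to 160 ± 13.8 (log2 fold change -4.24, SE 0.15, adjusted p = 0.000203). Car9, the hypoxia-induced carbonic anhydrase, fell from 4847 ± 333 to 451 ± 19.2 (log2 fold change -3.42, SE 0.13, adjusted p = 0.000224; -2.72 with the length trend removed). Cav1, the caveolin of the basal list, fell from 21100 ± 195 to 13833 ± 365 (adjusted p = 0.00847), a call lost in 8 of 18 other settings, among them without Scram C or any 1 shSLX4IP library (0.0522 to 0.0806), with a log2 fold change of -0.02 after quantile normalization. Drosha, the nuclear microRNA processing enzyme, fell from 1760 ± 65.2 to 982 ± 18.9 (adjusted p = 0.00770). Its call was lost in 2 of 18 other settings, among them quantile normalization (adjusted p = 0.0798). Zeb1, a repressor of epithelial genes, was at 690 ± 312 and 1450 ± 30.9 and did not pass (adjusted p = 0.0798), with Scram A the lowest at 349. It passed without Scram A (adjusted p = 0.00714), without Scram B (0.0487), after quantile normalization (0.0403), with DESeq2 (0.0154), among placed features only (0.0399) and with the length trend removed (0.0166). The epithelial regulator Grhl2 was low in both groups, at 48.9 ± 28.1 and 13.3 ± 9.26 (adjusted p = 0.177). Tgfbr1, Asns, Ndufa4 and Rpl30 did not pass either, with adjusted p of 0.228, 0.334, 0.156 and 0.124. Asns, with a log2 fold change of 0.28, passed with the length trend removed (log2 fold change 0.90, adjusted p = 0.000332), after quantile normalization (0.82, adjusted p = 0.00390) and without Scram A (0.49, adjusted p = 0.00535). Ndufa4, at -1.05, passed without Scram A (-0.51, adjusted p = 0.0174) and with DESeq2 (adjusted p = 0.0233), and was at -0.30 with the length trend removed. Rpl30 passed with DESeq2 alone (adjusted p = 0.0171). Ndufa4 and Rpl30 were highest in Scram A, and Rpl30 shares sequence with pseudogenes. Rpl30 was also at 493 in shSLX4IP C, against 5661 and 5165 in shSLX4IP A and B, and its log2 fold change of -2.73 was -1.58 without shSLX4IP C, -3.34 without shSLX4IP A and -2.14 without Scram A. Exons of Car9, Zeb1, Grhl2 and Rpl30 overlap other annotated genes on the other strand, and those of Drosha and Rpl30 genes on the same strand.

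**Figure D3:**
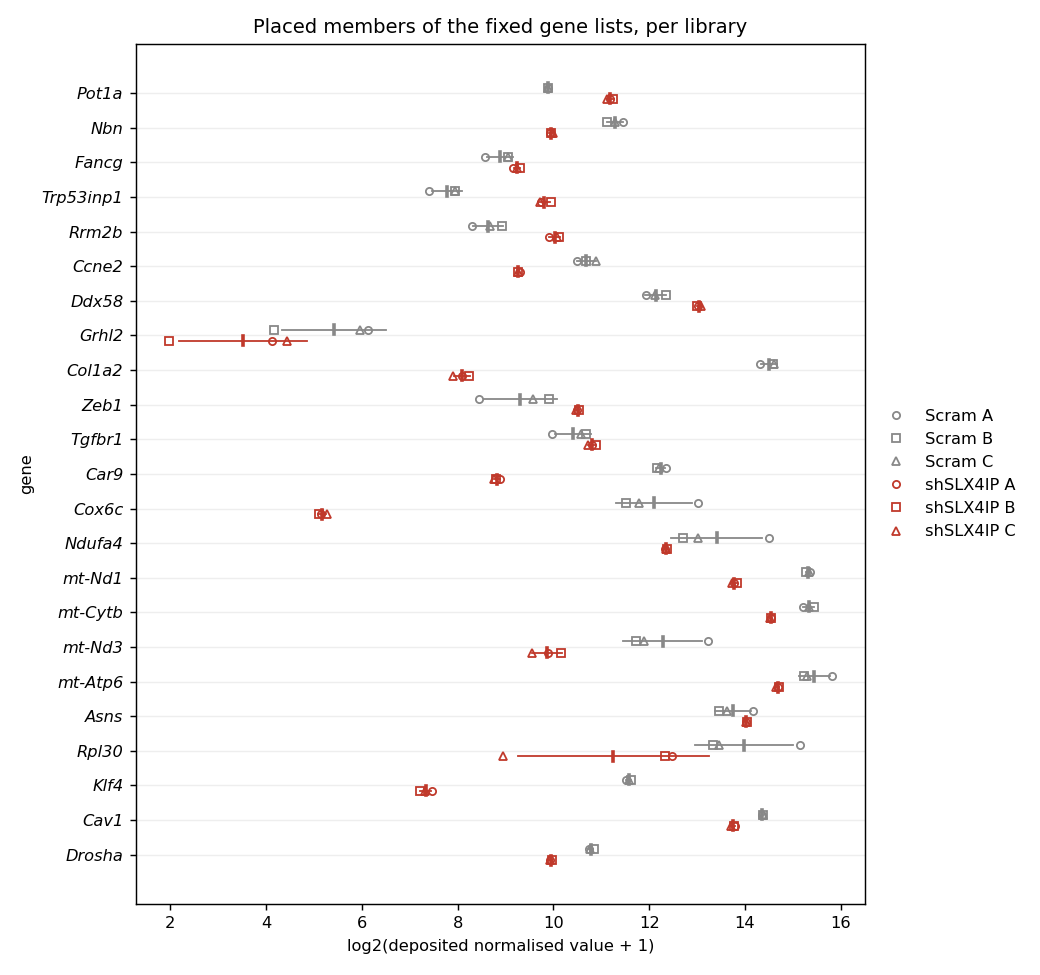
Values of the placed members of the fixed gene lists named in the text, except mt-Co1, which is not drawn, in each library, as log2(deposited normalised value + 1). Grey symbols are Scram and red symbols shSLX4IP, with a tick at the mean and a bar of 1 SD to each side (n = 3). Pot1a lies at 942 to 952 in Scram and 2221 to 2442 in shSLX4IP, and Scram A stands off the other Scram libraries for Ndufa4, Rpl30, mt-Nd3 and Zeb1, and shSLX4IP C off the other shSLX4IP libraries for Rpl30.

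Most mitochondrially encoded messages were lower in shSLX4IP. Of its 13 protein-coding genes 7 were lower and 1 higher over all features tested, and 9 were lower and 1 higher when adjusted over the list alone. The complex I gene mt-Nd1 (ENSMUSG00000064341.1, mitochondrial genome, 2751 to 3707) fell from 41016 ± 1249 to 13997 ± 519 (log2 fold change -1.55, SE 0.10, adjusted p = 0.000508). The fall of mt-Cytb was from 41208 ± 3242 to 23745 ± 209 (adjusted p = 0.00512), that of mt-Nd3 from 5608 ± 3491 to 945 ± 198 (adjusted p = 0.0150), and that of mt-Atp6 from 45367 ± 10662 to 26377 ± 632 (adjusted p = 0.0333). These 3 calls were lost without any 1 shSLX4IP library (adjusted p from 0.0515 to 0.150), and that of mt-Atp6 also without Scram C (adjusted p = 0.0765). Over 17 other settings mt-Cytb lost its call in 5, mt-Nd3 in 3 and mt-Atp6 in 7. The deposited values summed to 8.95e+06 in Scram A and to between 5.28e+06 and 5.97e+06 in the other libraries. The value of mt-Cytb in Scram A, 37977 against 23535 to 23953 in shSLX4IP, therefore depends on the size factor of Scram A. The one higher gene, mt-Co1 of cytochrome c oxidase, rose from 143800 ± 10159 to 188852 ± 3825 (log2 fold change 0.40, SE 0.10, adjusted p = 0.0363). It is named for being the one higher gene, after its value was seen. Annotated exons of mt-Nd1, mt-Atp6 and mt-Co1 overlap those of neighbouring mitochondrial genes. Short mitochondrial messages such as mt-Nd3 were highest in Scram A, at 9631 against 3382 and 3811 in Scram B and C. After quantile normalization, which moved the median log2 fold change of placed features from -0.23 to 0.06 and that of all features from 0.25 to -0.0028, mt-Nd1 kept its call and mt-Cytb and mt-Atp6 lost theirs without a change of sign. Over all settings the smallest fall was -0.35 for mt-Cytb and -0.12 for mt-Atp6, against -0.79 and -0.76 in the main test. The camera test of the list gave an adjusted p = 0.0374 downward over 33 lists, and adjusted p = 0.863 with an estimated correlation. It compared the list with the other features tested, most of which were not placed and cannot be read by gene. The median log2 fold change was 0.25 over all features and -0.23 over placed ones, so this comparison can itself favour a downward call. No other list was called by camera, and fry called 17 lists. The other 32 lists had at most 2 placed tested members each, so their tests are not read here.

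The libraries differed by group more than within it. Over the 8127 features the log2 values correlated at 0.870 to 0.877 within shSLX4IP and at 0.599 to 0.696 between the groups (across features, which are not independent replicates). Scram B and C correlated at 0.876, and Scram A correlated with them at 0.763 and 0.804. Over 353 placed nuclear genes with a mean of at least 100, the median log2 ratio of Scram A to the mean of Scram B and C was 0.84 in the third with the shortest exonic length and -0.27 in the third with the longest. The medians of Scram B over Scram C were -0.18 and 0.10 in the same sets of shortest and longest genes. In Scram A the 100 highest features took 44.1% of the values, against 35.6% and 37.0% in Scram B and C. By chromosome segment, 42 placed genes were higher and 54 lower on chromosome 4, 24 and 9 on chromosome 6, 10 and 29 on chromosome 15, and 3 and 6 on chromosome 18. A count test on the recovered reads called 1566 features with edgeR and 3226 with DESeq2.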

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

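Adjustment over placed features only, removal of a trend with exonic length and a segment threshold of 300 were chosen after the values were seen. No named gene reversed in any setting, and 27 of the 34 named genes called kept their call in each setting in which they were tested. The other 7 were Prrt4, Cav1, Ddx58, Drosha, mt-Cytb, mt-Nd3 and mt-Atp6. Slx4ip stayed at a difference of 0 with both other pseudocounts and without any of the libraries, and was not tested otherwise because the filter leaves it out. Both pseudocounts, TMM factors, quantile normalization, no filter, limma without the trend and edgeR kept each count of calls within 1.5 times. A mean of at least 50, which tests fewer features, gave 559 features at least 2-fold higher. DESeq2 called 1602 higher and 1624 lower, 1335 and 1253 of them at least 2-fold, and 165 placed features lower, and the cause was not tested. On the simulated reads DESeq2 made 44 false calls among 84 with the dispersion of all 6 libraries. With that of the libraries other than Scram A it made 45 among 145. Limma made 0 and 4 false calls, so calls by DESeq2 alone carry that limit. With the length trend removed, 143 placed nuclear features were higher and 127 lower, against 106 and 131 without the removal and adjusted over them alone, and 215 were called both ways with the same sign. A segment threshold of 300 placed 720 tested features, all 462 of the others among them, with 110 higher and 152 lower, 91 and 115 of them at least 2-fold, and kept 8 of the 10 highest and 9 of the 10 lowest genes.

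Leaving out 1 library gave 433 to 1895 features higher and 410 to 1573 lower, 425 to 1346 at least 2-fold higher and 391 to 933 at least 2-fold lower. Among placed features it gave 40 to 134 higher, 58 to 167 lower, and 39 to 74 at least 2-fold higher. The highest counts came without Scram A and the lowest without a shSLX4IP library, each from fewer samples. Without Scram C, 489 features were lower, 467 of them at least 2-fold, and 69 placed features were lower. Libraries with the same column letter did not deviate together, with correlations of deviations of -0.021, -0.0093 and -0.00073 for A, B and C, so the letters give no pairing. With the letter as a block, 365 features were higher and 309 lower, all at least 2-fold, and among placed features 35 were higher and 47 lower, all at least 2-fold. The block leaves fewer residual degrees of freedom.

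The call of the mitochondrial list is fragile. Its adjusted p was 0.0907 with a mean of at least 50, 0.857 after quantile normalization, 0.143 without the trend, 0.0533 with edgeR, 0.863 with an estimated correlation and 0.0600 among placed features only. It ran from 0.00187 without Scram A to 0.145 without Scram B. The number of lists called was 0 under the first 5 of these settings, 4 with DESeq2, 17 with fry, and 0 or 1 without a library. The cause was not tested. Between 5433573 and 6693111 reads were recovered per library and 1 read is worth 0.796 to 1.46 deposited units, so values of a few units rest on a few reads.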

Other observations

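Beyond the named genes, chosen here after their values were seen, these placed genes differed between the groups, and no list or theme was tested for them. Lyn, a Src-family kinase gene, rose from 212 ± 61.1 in Scram to 1514 ± 43.3 in shSLX4IP (limma adjusted p = 0.00137; its exons overlap a gene on the other strand), and Flnc, the actin crosslinker filamin C, from 3024 ± 430 to 11802 ± 623 (adjusted p = 0.000834). Rragd, a Rag GTPase gene of lysosomal nutrient sensing, rose from 260 ± 23.1 to 2051 ± 176 (adjusted p = 0.000404), and the ubiquitin-conjugating enzyme gene Ube2h from 3122 ± 56.7 to 9626 ± 337 (adjusted p = 0.000589). Cavin4, a caveola-associated protein gene, fell from 2322 ± 522 to 49.7 ± 7.32 (adjusted p = 0.000280), and the glycosyltransferase gene Galnt12 from 1238 ± 281 to 18.5 ± 4.95 (adjusted p = 0.000363).

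The tests of the following patterns were chosen after the results were seen, apart from the thinning of reads and the splits of the libraries. Genes that every cell uses were often listed at 0, 41.1% of 727 against 51.6% of 20963 other protein-coding genes, and 59.4% of the fixed list of cytosolic ribosomal proteins (19 of 32). Too few reads are argued against, since messages this abundant, Actb and Eef1a1 too, were at 0 in all 6 libraries of at least 5433573 reads. The feature under the identifier of Gapdh was not at 0, but it lies outside the segments and cannot be read as Gapdh. A candidate explanation is that the gene models were placed on another assembly than the reads. In 47 of 50 windows of 10 Mb the ubiquitous genes met the highest feature values at a shift other than 0, while 1 window each on chromosome 4 and chromosome 15 inside segments and 1 on chromosome 11 (50 to 60 Mb) outside them had theirs at 0. Any cause that leaves these genes without reads gives a best shift other than 0. None of the 47 matches was as sharp (z at most 6.27) as those inside segments (at least 6.86). A window with several different shifts would also lack a sharp match, so the scan cannot decide. The share of protein-coding genes scored as high fell on chromosome 4 from 48.7% at 55 to 60 Mb to 0% at 60 to 65 Mb. Such an edge goes with this explanation. At 0 to 5 Mb the share was 31.3% on chromosome 5 and 25% on chromosome 9, but 0% on chromosomes 10, 13 and X. The explanation stays open, and neither reads lost to pseudogene copies nor a biological explanation was tested.

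Scram A lay apart from the other 5 libraries. Fewer reads, or more reads in a few features, are argued against: after thinning to the reads that Scram A has outside its 100 highest features, Scram B and C still had 28.7% and 23.7% more features above 0. Exonic length correlated at -0.54 (Spearman, across 353 genes, which are not independent) with the ratio of Scram A to Scram B and C. It also correlated at 0.52 with that of Scram B to Scram C. A rank correlation does not give the size of a trend. In the 118 genes of shortest and the 118 of longest exonic length, the median log2 ratio of Scram A was 0.84 and -0.27. That of Scram B to Scram C was -0.18 and 0.10 in the same genes. The length trend was therefore larger in Scram A, though not confined to it. How much of the pattern the trend makes up stays open. As the whole cause a length trend is argued against by the lowest correlation within Scram, which was 0.935 with the trend removed and 0.924 before. Scram B with C stood at 0.967 both ways. What else set Scram A apart stays open, and no biological explanation was tested.

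Placed genes of chromosome 15 were lower in shSLX4IP than those of the other segments. The median log2 fold change of its 63 genes with a mean of at least 100 was -0.68 (quartiles -1.81 and -0.01), against -0.23 on chromosome 4, -0.20 on chromosome 18 and 0.32 on chromosome 6, which departed the other way. The difference was -0.45 from chromosome 4, -0.48 from chromosome 18 and -0.997 from chromosome 6, and without Scram A it was -0.55, -0.40 and -1.04. A candidate explanation, as a hypothesis from these data, is a different number of copies of this segment in the cells of the 2 groups. No value here decides it, since the segment was singled out for its low values, its genes did not shift by 1 common amount and 10 of them were called higher, so regulation of single genes stays open too.

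Some features were listed at 0 in each library of one group and at 50 or more in each of the other. They made up 1.95% of placed features, 5 of them at 0 in Scram and 4 at 0 in shSLX4IP. Over all features tested they made up 1.18%, 70 at 0 in Scram and 26 at 0 in shSLX4IP. Whether a listed 0 means absent expression was not tested. Cells of different origin, such as separate clones after selection, could give this pattern, and so could depletion of SLX4IP. These causes cannot be told apart, because any difference in origin between the cells of the 2 groups goes with the hairpin and Slx4ip itself cannot be read. The labels do not say whether more than 1 set of cells carried each hairpin. Over the 10 splits of the 6 libraries into 3 and 3, the real split called 1872 features and the highest other split 5. Only 1 split, the real one, called as many, and 10 splits are too few for a share under 0.05.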
